A study of Homo sapiens with 11 samples.

How the data were processed

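The samples were THP-1 cells, an established human line from a monocytic leukaemia, kept as monocytes or turned into macrophages with a phorbol ester (PMA), per the labels' protocols. Macrophages received PMA for 3 h and recovered for 24 h. Cells of both states then spent 24 h in hormone-stripped medium before 6 h of vehicle or 100 nM dexamethasone (Dex), a synthetic glucocorticoid. RNA was measured on the NanoString nCounter, which hybridizes a colour-barcoded probe to each transcript and counts the barcodes without amplification, from 50 ng of total RNA per sample. The series design names 12 samples with 3 replicates per group. The authors left out 1 macrophage sample treated with Dex because it grouped with the vehicle samples and showed no rise of FKBP5, so 11 samples were analysed here, 2 of them in the Dex-treated macrophage group (Mac_Dex). The other groups, vehicle-treated monocytes (Mono_Vehicle), Dex-treated monocytes (Mono_Dex) and vehicle-treated macrophages (Mac_Vehicle), held 3 samples each.

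The deposited values are a linear signal per probe, not raw counts. The authors used nSolver for quality control, per the labels; its version, the reference genes and the background rule are not given in the sources used here. The values themselves show how they were built: in each sample, 100% of the low values examined lay on a regular grid, within 0.1 of a step. An endogenous value therefore equals a sample factor times a net count, which is a whole count minus a fractional background. In macrophages the lowest value equalled the sample factor, as for net counts under 1 set to 1. In each monocyte sample, where the factor was under 1, the lowest value was 1. The sample factor ran from 0.659 to 0.965 in monocytes and from 1.21 to 1.52 in macrophages. Control probes carried the background subtraction but no sample factor. Because the background is unknown, whole counts were not recovered, and a count test was not run.

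The table held 608 probes, of which 594 were endogenous, 8 negative and 6 positive controls. Of the endogenous names, 565 are current symbols, 9 are older symbols such as IL8 (now CXCL8), and 20 matched neither and are used as they stand. Summed endogenous net counts before scaling ran from 412520 to 675213 per sample. A level of 20 units, set in the plan, was taken as the floor. Over all samples the negative controls reached at most 15.6, without the sample factor that endogenous values carry. That factor is larger in macrophages than in monocytes, so background on the endogenous scale comes nearer the floor in macrophages. Replicates of a group correlated with Pearson r from 0.984 to 0.992 on the log2 scale across genes, beside the r above 0.98 that the authors state. No 2 replicates were alike beyond sampling noise, with a chi-square per degree of freedom from 1.53 to 15.13. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be partly technical.

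Each of the 379 endogenous probes whose highest group mean was at least 20 was tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with lmFit, eBayes with a mean-variance trend, and Benjamini-Hochberg adjustment within each comparison. An adjusted p under 0.05 was called. All 4 groups entered 1 fit, so that Mac_Dex shared the estimate of the spread. The comparisons were Dex against vehicle in monocytes and in macrophages, and macrophages against monocytes with vehicle and with Dex. The difference of the responses was the interaction term. Log2 changes are on the log2(value + 1) scale. Where a group lies under the floor of 20 units, their size depends on the pseudocount. A fold printed in the text is the ratio of group means. For a gene with a group mean under 20, that mean was replaced by 20 and the fold is given as "at least". Values are given as mean ± SD, and log2 changes with their standard error (SE) where it matters.

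Gene lists were fixed before the data were examined: glucocorticoid-induced genes, pro-inflammatory cytokines, chemokines, chemokine receptors, interferon response, NF-kB pathway, innate sensors, MHC class II, MHC class I, complement, Fc receptors, macrophage markers, monocyte and progenitor markers, adhesion and migration, costimulation, TNF superfamily, JAK-STAT signalling, apoptosis, interleukin 1 family, TGF-beta signalling, housekeeping, and T, B and NK cell markers for lineages that the cultures should lack. Of these 24 lists, 22 had at least 5 tested members and were set against the other tested genes with camera (preset correlation 0.01, and again with an estimated correlation) and tested on their own with fry. The rule for named genes, fixed at the same time, took per comparison the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap (for the difference, among all called genes). It added FKBP5, CD163, DPP4, IL1B, TNF, CCL2, NFKBIA, TLR2 and CXCR4 everywhere, and up to 2 rising and 2 falling called members of each list, or the member with the smallest p where no member was called. TSC22D3, DUSP1 and NR3C1 were part of the rule, but the table has no probe under these names, so they could not be analysed. Some genes that the rule names are not reported here.

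Data were simulated from each gene's mean over the 4 groups and its real spread, with noise independent between genes. The fit then called 77.6% of genes changed 1.5-fold and 84.2% of those changed 2-fold with Dex in monocytes. It called 68.7% and 85.3% of them in macrophages, and 57.4% and 77.5% for the difference. Of unchanged genes it called 1.2% to 1.4%. In such simulations of the monocyte comparison, camera with the preset correlation called 1 of 440 unshifted lists. It called the NF-kB list, shifted by 0.5 on the log2 scale, in 20 of 20 runs. Estimated correlations within the real lists reached 0.73, so these rates do not carry over to correlated lists.

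Alternatives were 3 other scalings (each sample centred on its median over tested genes, the housekeeping list as reference, and quantile normalization), a pseudocount of 20, no filter and a filter at 100, values under 20 set to 20, eBayes without trend and with the robust option, sample weights, only the groups compared, the replicate number as a fixed or random block, an adjusted p under 0.01, a minimum of 1.5-fold, and each sample left out in turn. An alternative restricted to the 294 genes with a mean of at least 20 in all groups was chosen after seeing the data, as were camera with an estimated correlation under each scaling and the glucocorticoid-induced list without FKBP5. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the plots.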

Results

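Gene expression of a panel of immune genes was measured by nCounter hybridization in THP-1 monocytes and in macrophages made from them, each with vehicle or with 100 nM Dex for 6 h. The series title asks how glucocorticoids act differently on the activation of monocytes and macrophages. The 11 samples fell into Mono_Vehicle, Mono_Dex and Mac_Vehicle with 3 samples each and Mac_Dex with 2. Total normalized signal per sample was 372345 to 420466 units in monocytes and 742895 to 889658 in macrophages, and 379 of the 594 endogenous probes reached a mean of 20 units in at least 1 group. FKBP5, a co-chaperone of the glucocorticoid receptor and one of its best-known target genes, separated vehicle from Dex in each sample. It lay between 1205 and 1259 units in the 3 Mono_Vehicle samples, between 24832 and 24990 in Mono_Dex, between 407 and 623 in Mac_Vehicle, and at 38036 and 37306 in Mac_Dex. The Mac_Dex samples had been retained by the authors partly for their FKBP5 level, so its rise in macrophages is not independent evidence of a response.

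In monocytes, Dex raised classical glucocorticoid targets and lowered IL1B and several chemokine genes, among them IL8, CCL24 and CCL2. FKBP5 rose 20.1-fold, from 1237 ± 27.9 (SD, n = 3) to 24908 ± 79.2 units (SD, n = 3). ZBTB16, a zinc-finger transcription repressor, rose at least 47.2-fold to 944 ± 25.4 units. The neutrophil chemoattractant IL8 fell 13.7-fold, from 2917 ± 147 to 212 ± 21.5 units, and the eosinophil chemoattractant CCL24 fell 8.55-fold, from 353 ± 18.2 to 41.3 ± 10.2. In limma, 64 of 379 genes rose and 84 fell, and 174 had an unadjusted p under 0.05; 207 genes (54.6%) had groups that did not overlap, where chance gives 10%.

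Of the 9 tested glucocorticoid-induced genes, 7 rose, and 9 rose when adjusted over the list alone. Besides FKBP5 and ZBTB16 these included CXCR4, the receptor for the chemokine CXCL12 (log2 change 1.73, SE 0.07), NFKBIA, the inhibitor that holds NF-kB in the cytoplasm (1.46, SE 0.06), and the haemoglobin scavenger receptor CD163, which went from 1.00 to 39.3 ± 2.87 units, at least 1.96-fold. The list lay 2.26 above the other tested genes in mean log2 change (camera adjusted p = 3.36e-08, and adjusted p = 0.00912 with an estimated correlation, but adjusted p = 0.207 with an estimated correlation after centring samples on their medians). Without FKBP5 it had camera adjusted p = 1.56e-06, and adjusted p = 0.0516 with an estimated correlation. Other large rises were SLAMF1, a receptor of lymphocytes and phagocytes (at least 20.01-fold, to 400 ± 4.85 units), GNLY, a cytolytic granule protein (at least 26.4-fold, to 528 ± 3.93), SOCS1, an inhibitor of JAK-STAT signalling (at least 7.22-fold, to 144 ± 9.56), and the interleukin 1 receptor IL1R1 (at least 2.61-fold, to 52.3 ± 9.04).

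Of 15 chemokines, 8 fell and 2 rose, and 9 fell when adjusted over the list alone. CCL2, which attracts monocytes, fell at least 4.29-fold from 85.7 ± 14.9 units to the lowest value the table holds. CXCL1 and CXCL2, both neutrophil attractants, fell at least 2.86-fold and at least 4.05-fold. The list lay below the other genes (mean difference of log2 changes -1.24, camera adjusted p = 0.00857), and this was lost at adjusted p = 0.998 with an estimated correlation and at adjusted p = 0.202 with no filter on low values. Of 14 pro-inflammatory cytokines, 5 fell and 2 rose: IL1B fell at least 4-fold from 79.9 ± 12.4 units, and TNFSF13B, a B-cell survival factor, fell 2.77-fold to 72.0 ± 5.42. TNF fell by 0.55 on the log2 scale (adjusted p = 0.0178), a call that ended without Mono_Vehicle replicate 3 (-0.49, adjusted p = 0.0782) or Mono_Dex replicate 6 (-0.51, adjusted p = 0.0683). Of 15 interferon-response genes, 6 fell, among them the antiviral GTPase MX1 (250 ± 31.8 to 112 ± 10.7 units) and IRF8, a transcription factor of the monocyte lineage (3786 ± 117 to 2180 ± 61.3). That list had camera adjusted p = 0.0801 as deposited, and adjusted p = 0.0193 after median-centring, which gave adjusted p = 0.998 and 0.988 with an estimated correlation.

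Of 20 NF-kB genes, 3 rose and 4 fell, with RELB at -1.18 and BCL3 at -1.22 against NFKBIZ at 0.82 in log2 change. Of 23 innate sensors, 3 rose and 4 fell: TLR2, which senses bacterial lipoproteins, rose 1.66-fold to 1452 ± 16.8 units, while CD14, the lipopolysaccharide co-receptor, fell at least 2.67-fold. Rises and falls numbered 7 and 10 of 22 macrophage markers, 0 and 3 of 8 monocyte and progenitor markers, and 6 and 6 of 18 adhesion genes, where the integrin chain ITGA5 rose by 0.60 and ITGAL fell by 0.77 in log2. They numbered 7 and 5 of 26 JAK-STAT genes (IL13RA1 rose 2.09-fold), 2 and 5 of 13 TNF superfamily genes (TNFSF10, a death ligand, fell 2.48-fold), and 2 and 4 of 14 costimulation genes (CD40 fell by 0.88 in log2). They numbered 2 and 2 of 10 interleukin 1 family genes (5 and 2 when adjusted over the list alone; the antagonist IL1RN fell at least 2.69-fold), 2 and 4 of 13 complement genes, and 2 and 1 of 13 apoptosis genes (BCL2 fell by 0.64 in log2). The numbers were 1 and 1 of 7 Fc receptors (1 and 3 when adjusted over the list alone). FCGR1A/B, whose probe covers a gene pair, fell 2.90-fold. Rises and falls were 1 and 1 of 9 chemokine receptors and 1 and 2 of 7 TGF-beta genes. For 14 MHC class I genes they were 0 and 1 (0 and 0 when adjusted over the list alone). In limma none of 9 MHC class II genes and none of 6 B-cell markers passed, with 0 at an unadjusted p under 0.05 in each list. Of 16 housekeeping genes, GUSB rose and ALAS1, the first enzyme of haem synthesis, fell by 0.76 in log2. Mean and median differed in sign for innate sensors (mean -0.08, median 0.03), complement (0.13 and -0.04), JAK-STAT (0.01 and -0.03), MHC class II (0.06 and -0.08) and housekeeping (-0.02 and 0.01).

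In monocytes, the direction of weak changes depended on the scaling. Centring each sample on its median moved the median log2 change from -0.03 to 0.12, and the calls from 64 higher and 84 lower (43.2% higher) to 104 higher and 65 lower (61.5% higher). It turned complement from 2 higher and 4 lower to 5 and 1, costimulation from 2 and 4 to 6 and 2, TGF-beta genes from 1 and 2 to 2 and 0, MHC class I genes from 0 and 1 to 2 and 0, and monocyte and progenitor markers from 0 and 3 to 2 and 2. It also turned innate sensors from 3 and 4 to 7 and 4, and moved the interleukin 1 family from 2 and 2 to 6 and 2 and housekeeping genes from 1 and 1 to 4 and 1. Quantile normalization gave 6 and 4 for innate sensors, 4 and 3 for costimulation, 4 and 8 for adhesion genes and 2 and 6 for housekeeping genes. After median-centring 9 glucocorticoid-induced genes were higher. Without FKBP5 these were 8 of 8 after median-centring and 7 of 8 with quantile normalization.

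**Figure D1:**
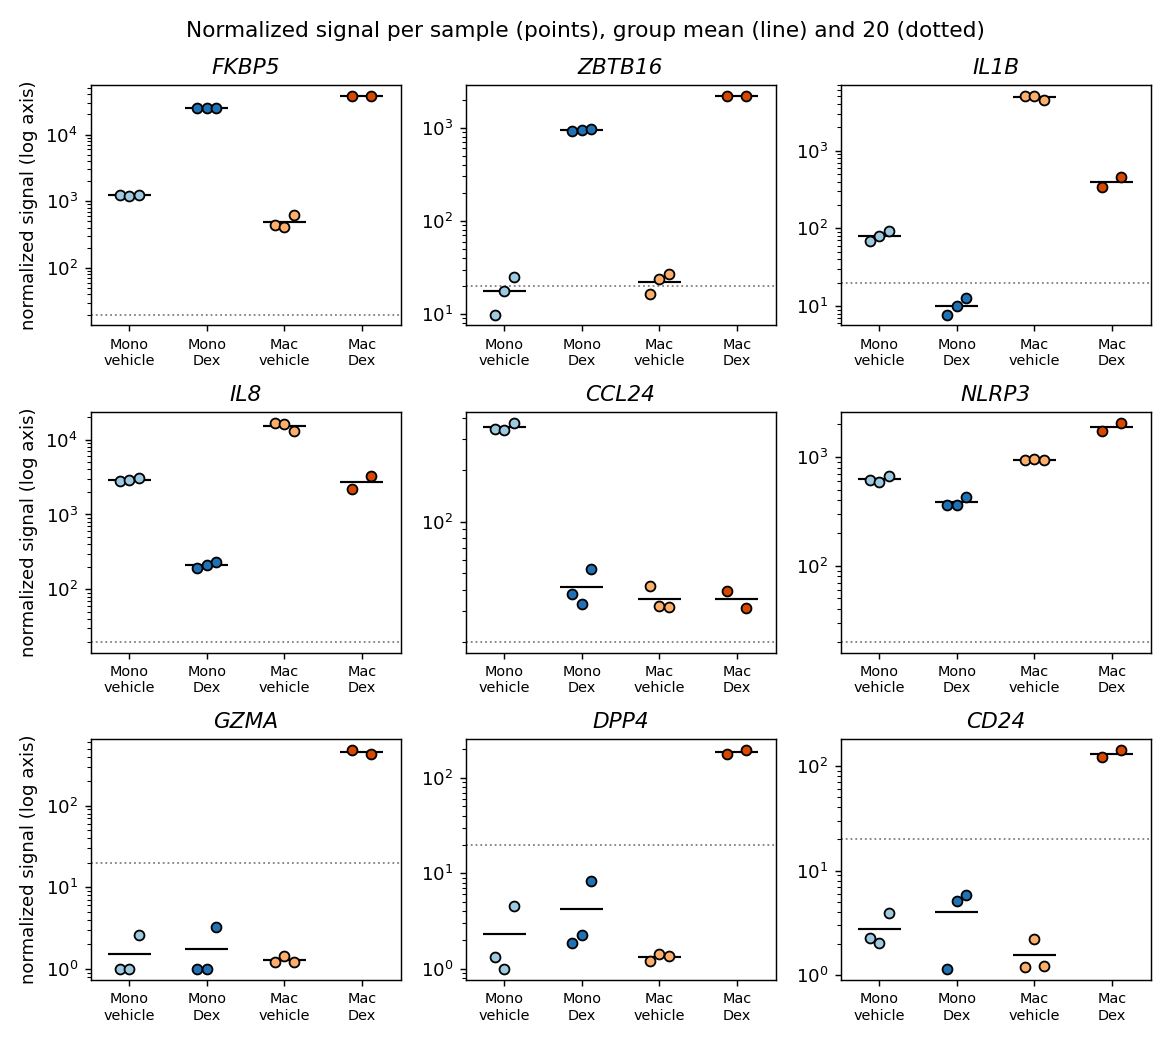
Normalized signal (units, log axis) of FKBP5, ZBTB16, IL1B, IL8, CCL24, NLRP3, GZMA, DPP4 and CD24 in each of the 11 samples, as points by group, with a line at the group mean and a dotted line at the floor of 20 units. FKBP5 lies at 24832 units or more in all 5 Dex samples, and GZMA is above the floor in the 2 Mac_Dex samples alone, at 479 and 434 units.

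In macrophages, the same glucocorticoid targets rose, and 3 genes that were near the floor in the other groups appeared. FKBP5 rose 77.1-fold, from 488 ± 117 (SD, n = 3) to 37671 ± 516 units (SD, n = 2), and ZBTB16 97.8-fold, from 22.3 ± 5.33 to 2185 ± 10.6. The vehicle mean of ZBTB16 lies near the floor of 20 units, so the size of its fold is uncertain. GZMA, a granule protease of cytotoxic lymphocytes, reached 457 ± 31.9 units, at least 22.8-fold. DPP4, a cell-surface peptidase, reached 185 ± 12.6, at least 9.26-fold, and CD24, a surface glycoprotein, reached 131 ± 14.5, at least 6.53-fold. IL1B fell 12.3-fold, from 4856 ± 327 to 396 ± 79.8 units, and the adhesion molecule ICAM1 fell 5.32-fold, from 1358 ± 109 to 255 ± 66.0. In limma, 85 genes rose and 95 fell, 202 had an unadjusted p under 0.05, and 222 (58.6%) had groups that did not overlap, where chance gives 20% for 3 samples against 2.

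Of the 9 glucocorticoid-induced genes 8 rose, and 8 when adjusted over the list alone (camera adjusted p = 1.09e-06, and adjusted p = 0.0173 with an estimated correlation, but with an estimated correlation adjusted p = 0.339 after median-centring and 0.0676 with the housekeeping list). Without FKBP5, for whose rise samples had been kept, 7 of 8 rose (camera adjusted p = 2.9e-05, and adjusted p = 0.0937 with an estimated correlation). The sample left out had also grouped with vehicle samples, so the other rises are not free of that choice. CXCR4 rose 4.24-fold to 1850 ± 66.4 units, CD163 3.69-fold to 653 ± 79.3, and NFKBIA 1.62-fold to 8150 ± 474. GNLY rose 6.98-fold to 799 ± 10.7 units, SOCS1 9.16-fold to 703 ± 10.7, SLAMF1 at least 14.3-fold to 286 ± 16.8, and C1QB, a chain of complement C1q, at least 1.89-fold to 37.7 units. No other list passed camera in this comparison: 2 of 22 lists had an unadjusted camera p under 0.05, and fry called 4 lists after adjustment.

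Of 14 pro-inflammatory cytokines, 7 fell and 1 rose in macrophages. TNF fell 1.71-fold (adjusted p = 0.00211), and TNFSF15, a TNF-family ligand, fell 5.04-fold to 30.4 units. LIF, low in these cells, fell at least 1.30-fold, and IL15 rose at least 2.13-fold. Of 15 chemokines, 7 fell and 1 rose (camera adjusted p = 0.386, and adjusted p = 0.0478 after median-centring; adjusted p = 0.975 and 0.501 with an estimated correlation): IL8 fell 5.57-fold to 2740 ± 760 units and CCL2 at least 3.87-fold, while CCL24 stayed at 35.3 ± 5.79 with vehicle and 35.5 ± 5.60 with Dex (adjusted p = 0.978). Of 13 TNF superfamily genes, 8 fell and 1, the lymphotoxin receptor LTBR, rose. NF-kB genes divided, 4 rising and 7 falling of 20: NFKBIZ rose 4.08-fold to 556 ± 68.6 units, while BCL3 fell 5.11-fold and the adaptor TRAF1 at least 6.04-fold. The mean log2 change of that list was -0.20, its median 0.12 and camera's direction up.

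Of 23 innate sensors, 6 rose and 4 fell. TLR2 rose 2.24-fold to 5542 ± 462 units and IRAK3, an inhibitory kinase homologue of Toll-like receptor signalling, 3.22-fold to 523 ± 18.2, while CD14 fell 4.29-fold to 43.9 ± 4.10 and TLR1 fell by 1.31 in log2. Among 13 complement genes, 5 rose and none fell, here and at an unadjusted p under 0.05 in limma (5 and 0); CFP, which stabilizes the alternative-pathway convertase, rose 3.85-fold. With the housekeeping list or quantile normalization, 2 complement genes fell. Rises and falls numbered 4 and 7 of 22 macrophage markers (5 and 10 when adjusted over the list alone). They numbered 0 and 2 of 8 monocyte and progenitor markers (KIT fell by 1.10 in log2) and 3 and 3 of 18 adhesion genes (ITGA5 rose 2.59-fold to 20594 ± 32.4 units). They numbered 1 and 4 of 9 chemokine receptors, where the fractalkine receptor CX3CR1 fell 3.12-fold to 114 ± 11.2. They numbered 8 and 8 of 26 JAK-STAT genes (CSF2RB, the shared chain of the GM-CSF receptor, fell 2.63-fold), 4 and 4 of 10 interleukin 1 family genes (IL1R1 rose 5.07-fold), 3 and 2 of 13 apoptosis genes (the survival factor MCL1 rose 1.71-fold as deposited but not with quantile normalization, at 0.08 in log2 and adjusted p = 0.206), and 2 and 4 of 14 costimulation genes (CD40 fell by 1.14 in log2). They numbered 0 and 2 of 15 interferon-response genes and 0 and 3 of 7 Fc receptors. They numbered 2 and 1 of 7 TGF-beta genes (the repressor SKI rose by 0.61 and the receptor TGFBR1 fell by 0.71 in log2). They numbered 1 and 0 of 14 MHC class I genes (0 and 0 when adjusted over the list alone), 0 and 1 of 9 MHC class II genes, and 1 and 2 of 6 B-cell markers. Of the 16 housekeeping genes, SDHA, OAZ1 and GUSB rose and ALAS1 fell 1.86-fold; OAZ1 changed sign with quantile normalization, and the rise of GUSB ended without Mac_Dex replicate 1 (0.16, adjusted p = 0.153). The tested T-cell markers were TBX21, which rose, and IL7R, which fell (a call that ended without Mac_Dex replicate 1, at -0.81 and adjusted p = 0.0608), and the tested NK-cell markers were GNLY and GZMA, which rose, and NCAM1, which fell by 0.30 in log2; in monocytes IL7R fell and GNLY rose.

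In macrophages too the balance of calls moved with the scaling. Median-centring shifted the median log2 change from -0.03 to 0.19 and the calls from 47.2% higher to 67.3% higher (152 higher and 74 lower); with it, NF-kB genes were 12 higher and 7 lower, innate sensors 11 and 3, macrophage markers 6 and 5, costimulation 4 and 3, monocyte and progenitor markers 4 and 2, MHC class II genes 2 and 1, and B-cell markers 4 and 1. Also with it, MHC class I genes went from 1 higher and 0 lower to 8 and 0, housekeeping genes from 3 and 1 to 9 and 1, and JAK-STAT genes from 8 and 8 to 10 and 4. Interferon-response genes went from 0 and 2 to 2 and 2, and Fc receptors from 0 and 3 to 1 and 1. Quantile normalization gave 9 and 7 for NF-kB genes, 3 and 1 for B-cell markers, 4 and 8 for adhesion genes, 3 and 4 for apoptosis and 3 and 5 for housekeeping genes, and the housekeeping list gave 2 and 3 for TGF-beta genes. Mean and median log2 change also differed in sign for innate sensors (-0.03 and 0.09), JAK-STAT genes (0.12 and -0.04), apoptosis (-0.09 and 0.07), the interleukin 1 family (-0.11 and 0.03) and MHC class I (0.01 and -0.01). Without Mac_Dex replicate 1, 67 genes fell instead of 95.

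Across the 379 genes, the Dex responses of monocytes and macrophages had a Pearson r of 0.65 and a Spearman rho of 0.61; these are correlations across genes, which are not independent replicates. Of the calls, 47 genes rose in both cell states and 55 fell in both, against 14.4 and 21.1 for independent lists, and 8 went opposite ways, against 34.9. The opposite genes were BCL6, CDKN1A, IL18 and IL4R, which rose in monocytes and fell in macrophages, and CD59, NLRP3, NOD2 and NOTCH2, which did the reverse; CDKN1A, IL4R and NOTCH2 were named after their values were seen. NLRP3, the inflammasome sensor, went from 624 ± 37.6 to 385 ± 36.4 units in monocytes and from 950 ± 3.57 to 1908 ± 216 in macrophages. NOTCH2 went from 1655 ± 40.6 to 1378 ± 19.3 and from 2156 ± 138 to 4054 ± 180 units. BCL6, a transcription repressor, went from 37.7 ± 4.70 to 58.7 ± 14.2 and from 747 ± 97.6 to 382 ± 32.9. The signs of these 8 genes were kept with each of the other scalings. Signs alone were compared, and after median-centring 74 of the 95 falls in macrophages stayed called.

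**Figure D2:**
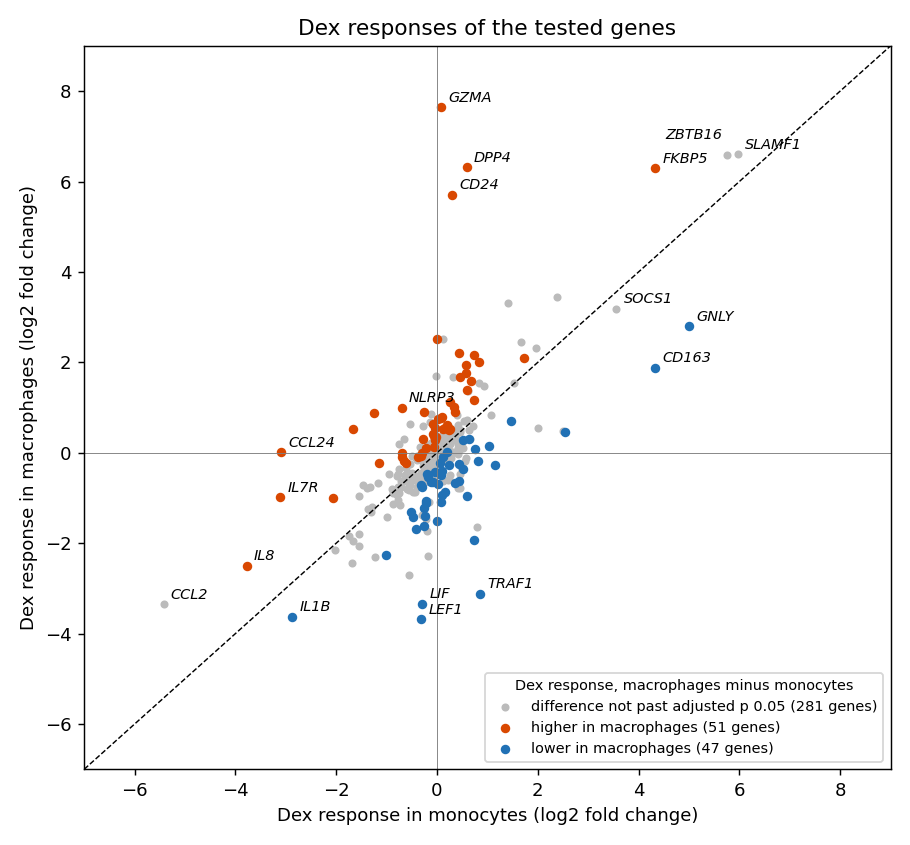
Log2 change with Dex in monocytes (x axis) against that in macrophages (y axis) for the 379 tested genes, 1 point per gene, coloured by the test of the difference. It is more positive in macrophages for 51 genes, more negative for 47 and not past the threshold for 281.

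The difference of the responses was tested directly. GZMA, DPP4 and CD24 rose in macrophages but stayed under 10 units in each monocyte sample (adjusted p of the difference 1.56e-06, 8.1e-05 and 6.43e-05). Their log2 differences are not measured, since 3 of the 4 groups lie under the floor. CCL24 fell in monocytes and not in macrophages, where it was already low with vehicle (difference 3.10, adjusted p = 4.52e-06). FKBP5 rose more in macrophages (1.96, SE 0.17), where the samples had been kept partly for its rise, so no p is given. More positive were also NFKBIZ (1.19), the properdin gene CFP (1.38), ITGA5 (0.78), JAK1 (0.86) and MCL1 (0.68). NLRP3 (1.70), NOD2 (2.14) and IL8 (1.28), and IL7R with a group under the floor, were also more positive in macrophages. The interferon-gamma receptor chain IFNGR1 (-0.88), NFKBIA (-0.77), CX3CR1 (-1.37), TLR4 (-0.95), TLR1 (-0.80), KIT (-1.19) and POU2F2 (-1.04) were more negative, as was GNLY with a group under the floor. In limma 51 genes were more positive and 47 more negative, with 136 at an unadjusted p under 0.05. With the replicate number as a fixed block these were 28 and 21.

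Among the glucocorticoid-induced genes 5 responded more positively in macrophages and 2 more negatively (NFKBIA and CD163), as when adjusted over the list alone. CD163 is at the floor in vehicle-treated monocytes and turned to 0.94 (adjusted p = 0.00179) with values under 20 set to 20. Among chemokines 4 responded more positively (4, with 1 more negative, over the list alone), among complement genes 3, and among the TNF superfamily 3 more negatively. No list passed camera for the difference, where 0 of 22 lists had an unadjusted p under 0.05; fry called 5 lists unadjusted and 0 after adjustment. With values under 20 set to 20, the glucocorticoid-induced list passed camera (adjusted p = 0.0292, and adjusted p = 0.266 with an estimated correlation). That list holds FKBP5, for whose rise samples had been kept, and this setting was not run without it. As deposited and without FKBP5, 4 of 8 genes were more positive and 2 more negative. Camera then gave adjusted p = 0.861, and adjusted p = 0.994 with an estimated correlation. Median-centring moved the split from 52% more positive to 63.5% (73 and 42 genes), turned the NF-kB genes from 2 more positive and 4 more negative to 8 and 4, and turned macrophage markers from 4 and 6 to 6 and 5. Without Mac_Dex replicate 1 the genes more negative in macrophages numbered 29 instead of 47.

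Macrophages and monocytes with vehicle differed in most tested genes, in a direction that depended on the scaling. As deposited, 247 genes were higher in macrophages and 74 lower (76.9% higher, median log2 difference 0.72). With median-centred samples these were 149 and 178 (45.6% higher, median -0.20), with quantile normalization 148 and 182 (44.8%, median -0.29), and with the housekeeping list 207 and 105 (66.3%, median 0.40). Apart from TNF, the genes of this paragraph kept their direction under each scaling. The scavenger receptor MSR1 went from 1.00 to 9677 ± 459 units, at least 484-fold. The secreted phosphoprotein SPP1 was 549-fold higher, at 138 ± 17.96 and 75504 ± 3336, HAVCR2, an inhibitory receptor, 114-fold to 5249 ± 232; and the lectin-like B-cell receptor CD22 at least 45.3-fold to 906 ± 81.0. IL1B was 60.7-fold and ICAM1 50.1-fold higher. CCL20 was at least 44.2-fold, LY96, the partner of TLR4, at least 20.9-fold, and the guanylate-binding protein GBP1 at least 10.6-fold higher. Lower in macrophages were the calprotectin subunits S100A8 (at least 17.0-fold) and S100A9 (16.3-fold), the granule protease CTSG (8.59-fold, 11281 ± 540 to 1313 ± 109 units), CCL24 (10.01-fold), MAP4K1 (6.52-fold), PTPN22 (5.13-fold) and the chemokine receptors CCR2 (3.51-fold) and CXCR2. FKBP5 was lower by -1.36 in log2, and CXCR4 by -1.71. TNF was 0.47 higher as deposited (adjusted p = 0.0185), not past the threshold without Mac_Vehicle replicate 1 (0.39, adjusted p = 0.0744), and lower after median-centring (-0.44) or quantile normalization (-0.44).

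By list, 20 of 22 macrophage markers were higher and none lower, with 19 and 0 after median-centring and 19 and 1 with quantile normalization (camera adjusted p = 0.001). Of 8 monocyte and progenitor markers 7 were lower and 1, the transferrin receptor TFRC, higher under each scaling (camera adjusted p = 0.000116). Of 15 interferon-response genes 14 were higher and 1, IRF8, lower under each scaling; camera gave adjusted p = 0.15 as deposited and adjusted p = 0.00258 after median-centring, which became adjusted p = 0.97 and 0.82 with an estimated correlation. Of 9 MHC class II genes 2 were higher and 5 lower, with HLA-DRA at -2.13 and HLA-DQB1 at least 2.32-fold lower, and the protease CTSS at 2.25 (camera adjusted p = 0.0326, fry direction up); median-centring gave 1 and 7. Of 18 adhesion genes 17 were higher and 1 lower (12 and 4 after median-centring; camera adjusted p = 0.0188), and of 9 chemokine receptors 2 were higher and 5 lower (2 and 6; camera adjusted p = 0.0188). All 14 MHC class I genes were higher as deposited (camera adjusted p = 0.0326) but 6 were higher and 4 lower after median-centring. None of these 6 camera calls held with an estimated correlation, where the adjusted p was 0.533 for the monocyte and progenitor markers, 0.955 for the chemokine receptors and 0.97 for the others; fry, which does not compare a list with other genes, called all 22 lists. Of the 16 housekeeping genes, 8 were higher and 2 lower as deposited, and 3 higher and 13 lower after median-centring. Lists with mostly higher genes as deposited that turned on median-centring were NF-kB (15 higher and 2 lower to 6 and 12), JAK-STAT (22 and 3 to 12 and 13), innate sensors (12 and 7 to 8 and 10), complement (7 and 3 to 4 and 7), apoptosis (9 and 3 to 2 and 8), TGF-beta (5 and 2 to 2 and 4) and B-cell markers (3 and 1 to 2 and 4). Fc receptors, 3 higher and 4 lower, had a mean of 0.53 and a median of -1.25.

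With Dex, 234 genes were higher in macrophages and 68 lower (77.5% higher, median log2 difference 0.75); median-centring gave 145 and 168 (46.3%, median -0.09), quantile normalization 139 and 184 (43%, median -0.25) and the housekeeping list 201 and 111 (64.4%, median 0.40). MSR1, SPP1, HAVCR2, CD22, LY96 and GBP1 were again among the 10 largest differences. They were joined by GZMA (at least 22.8-fold) and CSF1, the macrophage growth factor (at least 19.2-fold). The rank of a gene under 20 units in monocytes depends on the pseudocount, as for GZMA (1.75 units in Mono_Dex) and CD22 (1.54). All 22 macrophage markers were higher as deposited (18 and 0 lower after median-centring; camera adjusted p = 0.000309, and adjusted p = 0.794 with an estimated correlation), and 7 of 8 monocyte and progenitor markers were lower under each scaling (camera adjusted p = 2.55e-05, and adjusted p = 0.401 with an estimated correlation). FKBP5 was 0.60 higher in log2 as deposited and -0.24 after median-centring.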

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

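The tests of explanations in this part were chosen only after the results were seen; the interaction test, the floor setting and the single samples left out were planned. The responses to Dex differed between the cell states by the interaction test, with 51 genes more positive in macrophages and 47 more negative. With the replicate number as a fixed block these were 28 and 21. Among the differences in log2 change computed with a pseudocount of 1, those above 0 were GZMA 7.57, DPP4 5.73, CD24 5.41, CCL24 3.10, IL15 2.5, CSF1 2.21, NOD2 2.14, IL7R 2.12, FKBP5 1.96 and DEFB1 1.77. Those below 0 were TRAF1 -3.98, LEF1 -3.37, LIF -3.04, HLA-DPA1 -2.67, CD163 -2.45, GNLY -2.20, EOMES -2.08, BCL6 -1.56, TNFRSF9 -1.50 and LTA -1.42. Genes followed in each comparison that also differed were IL1B -0.75, NFKBIA -0.77, TLR2 0.43 and CXCR4 0.35. Where a group lies under 20 units, the size and order of these values depend on the pseudocount: with values under 20 set to 20, GZMA is 4.44, DPP4 3.15, CD24 2.64, CSF1 0.54, IL7R 1.13, TRAF1 -2.54, LEF1 -0.61, GNLY -1.84 and IL1B -1.69. The signs of CD163, DEFB1 and EOMES turn under that setting, so their printed values give no direction. IL15, LIF, HLA-DPA1 and LTA lost the call with values under 20 set to 20, and IL1B and CXCR4 lost it without several single samples. The negative control probe NEG_F, which no comparison uses, read between 7.97 and 15.6 units over the 11 samples, before any sample factor. Its median was 12.57.

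GZMA, DPP4 and CD24, genes best known from lymphoid cells, appeared in Dex-treated macrophages alone, where lymphoid cells would bring their lineage markers. None of 16 lineage markers, picked from 52 lymphoid genes after the values were seen, rose. Among the 14 under 20 units in Mac_Vehicle the highest value in a Mac_Dex sample was 13.34. All samples were of an established monocytic line, which should hold no lymphoid cells. The marker values also argue against such cells as the source. By themselves they do not exclude them, since markers and rule were chosen from these same data. Of the other lymphoid genes TBX21 (20.2 to 61.6 units) and GNLY (114 to 799) did rise; GNLY also rose in monocytes. A first form of that test took the highest of all lineage markers, 2811 units for NCAM1, and was replaced once its value had been seen, because NCAM1 is high in these cells with vehicle too. Cross-hybridization of the FKBP5 transcript is excluded. In Mono_Dex the 3 genes reached at most 8.39 units, where the FKBP5 level would give 302, 122 and 86.4. The rise came with Dex against vehicle, in 2 samples kept partly for their FKBP5 level. Whether it depends on the glucocorticoid receptor was not tested, and a receptor antagonist could test it.

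Most tested genes were higher in macrophages than in monocytes as deposited, by a median of 0.72 in log2. Before scaling, the median difference of net counts was 0.077, within the SD of 0.193 between sample medians of a group, while the sample factors differ by 0.668, so the factors may account for most of the shift. The rule for this test first asked for a difference of 0 or less and was changed after the value was seen. What set these factors stays open, since the reference genes are not given. The housekeeping list has a median difference of 0.126, with genes from -0.66 to 1.85, and the positive controls differ by 0.062. Each sample held 50 ng of total RNA, so total RNA per cell would not by itself shift these counts. The authors' list of reference genes would be needed to test their part.

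The differing responses to Dex could also come from values near the floor or from the choice of samples. Among genes of at least 20 units in all groups, 26.5% passed the interaction test (78 of 294), beside 23.5% of the others (20 of 85; Fisher exact p = 0.673), so the floor is excluded as the sole cause. With 1 Mac_Dex sample left, the fit called at least 83 genes. Some of these were not among the main calls, and part of the main calls was lost. The sample left out by the authors was not analysed here, and how far its exclusion might have shaped these differences stays open. Repeating the treatment in more macrophage cultures would test it.

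Of the 10 ways to split 6 samples into equal groups, the real split had 148 calls with Dex in monocytes and 0 at most in the other splits. Between the cell states with vehicle it had 321 calls and 0 at most. With 10 splits the real one can have a share of 1 in 10 at best, too few for a share under 0.05. Every other split also puts samples of both real groups together, so real effects would raise the spread within its groups. The 0 calls there therefore do not show what chance alone would give.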

How the results depend on the processing

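Of the tests in this part, the restriction to genes of at least 20 units in all groups alone was chosen only after the result was seen. Among the gene counts, FKBP5 values and the correlation of responses, 210 values under the alternatives were labelled as kept, 25 as moved, 3 as weakened and 1 as reversed. With 1 sample left out, 174 were labelled as kept and 2 as moved. A gene count labelled as kept could still change. Without Mono_Dex replicate 6, 52 genes instead of 64 rose with Dex in monocytes. Without Mac_Vehicle replicate 5, 112 instead of 95 fell in macrophages. Where a call or direction changed, the cause was not tested unless given. Values near the floor limit low genes: the negative controls reach 15.6 units before the sample factor, which is larger in macrophages.

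Median-centring gave 104 higher genes with Dex in monocytes and 152 in macrophages, and macrophages against monocytes 149 higher and 178 lower with vehicle and 145 and 168 with Dex. Quantile normalization gave 148 and 182 with vehicle and 139 and 184 with Dex, and the housekeeping list 111 lower with Dex; median-centring and quantile normalization remove a shift between samples by construction, while the housekeeping list leaves a median of 0.40 between the cell states. FKBP5 in macrophages against monocytes with Dex was 0.60 as deposited, -0.24 median-centred, 0.24 with the housekeeping list, 0.17 with quantile normalization and 0.34 with the fixed replicate block. TNF with vehicle reversed to -0.44 median-centred and -0.44 quantile-normalized, HLA-DOB with vehicle to -0.20 and -0.49, and NFKBIA with Dex to -0.20 and -0.49. A reversal is a change of sign alone. In limma the median-centred value had adjusted p = 0.00506 for TNF and adjusted p = 0.487 for HLA-DOB. For the difference of responses, CD163 reversed to 0.28 with a pseudocount of 20 and 0.94 with values under 20 set to 20, which also reversed DEFB1 to -0.032 and EOMES to 0.105; these genes have a group near the floor.

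The correlation of the responses was 0.731 with a pseudocount of 20, 0.718 with values under 20 set to 20, 0.690 with a filter at 100, 0.597 with no filter, 0.616 without Mac_Dex replicate 1, 0.656 without Mac_Dex replicate 5, and 0.706 over genes of at least 20 units in all groups, an alternative chosen after seeing the data. Stricter rules give fewer calls by construction: an adjusted p under 0.01 left 31 and 28 genes for the difference, and a minimum of 1.5-fold left 30 higher and 46 lower in monocytes, 45 higher in macrophages and 31 more positive for the difference. The fixed replicate block gave 28 and 21 genes for the difference, of which 28 and 20 were among the main calls, and 43 lower in macrophages with Dex. Between vehicle and Dex, replicates of the same number shared deviations with r of 0.23 and 0.18 in monocytes. In macrophages r was -0.28 and -0.41. These pairs are too few to tell whether the numbers pair the samples.

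With 1 sample left out, calls ran from 52 to 65 higher and 74 to 91 lower in monocytes, 72 to 99 and 67 to 112 in macrophages, 34 to 62 and 29 to 52 for the difference (29 without Mac_Dex replicate 1), 237 to 253 and 68 to 78 between cell states with vehicle, and 214 to 236 and 53 to 71 with Dex. FKBP5 ran from 4.31 to 4.34 in monocytes and from 6.17 to 6.48 in macrophages. Of the named-gene values under the other alternatives, 4338 were the same, 213 weaker, 9 stronger and 10 reversed, and of the list values 1062, 23 weaker and 10 stronger. With 1 monocyte or Mac_Vehicle sample left out, from 11 (without Mac_Vehicle replicate 5) to 21 named-gene values (without Mono_Dex replicate 2) weakened. In these settings 344 and 335 were the same. Not run were edgeR on counts, and camera with the robust option, the random block, only the groups compared, and the genes of at least 20 units in all groups.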

Other observations

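Genes outside the fixed lists also responded to Dex; those named here were chosen after their values were seen. PLAU, the urokinase that activates plasmin, fell in both cell states (log2 change -1.67 in monocytes and -1.96 in macrophages), and so did EGR1, an immediate-early transcription factor (-0.87 and -0.89), and the prostaglandin E2 receptor PTGER4 (334 to 168 units in monocytes and 918 to 341 in macrophages). CD83, a marker of mature dendritic cells, fell from 266 to 133 units in monocytes and from 644 to 134 in macrophages (difference -1.25, adjusted p = 8.1e-05, limma). PPARG, a lipid-sensing nuclear receptor, rose by 0.63 and 0.51, and AHR, the aryl hydrocarbon receptor, by 0.38 and 0.47.

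The potassium channel gene KCNJ2 rose from 62 to 92 units in monocytes and from 192 to 652 in macrophages, a difference of 1.18. The lysosomal protease CTSC rose in macrophages (0.75) and not in monocytes (0.03, adjusted p = 0.666, limma). In macrophages, NOTCH1 (-0.86) and NFATC3 (-0.66), a calcium-regulated transcription factor, fell.

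The test of this part was chosen only after the result was seen. Dex in macrophages lowered many genes that are higher in macrophages than in monocytes: of 247 such genes 72 fell and 54 rose, and of 74 lower genes 11 fell and 16 rose, beside 95 falling and 85 rising of all 379. The excess of falls depends on the scaling: after median-centring 39 of 149 higher genes fell and 44 rose, and 27 of 178 lower genes fell and 88 rose. Quantile normalization gave 64 falls and 28 rises of 148 higher genes, and the housekeeping list 74 and 50 of 207. Both differences use the same vehicle samples, which alone gives a negative covariance. The covariance across genes was -0.526, outside the simulated range of -0.113 to 0.04 from shared samples. Over genes of at least 20 units in all groups it was -0.152, outside -0.031 to 0.015. The simulation held no Dex effect in macrophages and drew genes independently. A Dex response unrelated to the cell state could therefore also fall outside these ranges. Whether Dex acts in part against the macrophage state stays open. The Pearson r of -0.21 is low, and vehicle samples split between the comparisons would remove the shared term.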
